A study of Rattus norvegicus with 4 samples.

How the data were processed

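Total RNA from the liver of male Wistar rats aged 4 months was measured on Illumina expression BeadArrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment, and labelled as biotinylated cRNA with a TargetAmp kit. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. There were 4 groups with 1 deposited sample each: control offspring on standard diet, control offspring on high-fat diet, and prenatally undernourished (FR30) offspring on each of these diets.

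The authors deposited a normalized table of signal intensity per gene, with a standard deviation (STDEV) of that intensity and a detection p-value for each sample, per the file headers. Their normalization method and the number of measurements behind each STDEV are not given in the sources used here. The values keep their background: the mean of the negative control beads implied by the detection p-values lay between 153 and 154 on all 4 samples. The series matrix holds the same deposited intensity, equal within 0.01 for all 21791 genes. The authors also deposited a table of non-normalized intensity with a detection p-value per probe. By identifier its values lay within 2-fold of the normalized table without a break only for the first 34 rows: matched by identifier, its log2 intensity correlated with the normalized table at Pearson r between 0.0587 and 0.0658 across 21791 rows. Matched by row order, which an alignment of both tables gave for 20442 genes with 1 row, r lay between 0.99858 and 0.99998. The alignment kept the order of rows and chose pairs by their signals, so a high r is in part built in. It left 702 genes with no row and gave 647 genes several.

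The normalized table therefore took the place of the non-normalized one as the starting point, which departs from the design fixed before the data were examined. The non-normalized values put to genes by row order served as an alternative chosen after seeing the data. Background was corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, as its neqc function does from detection p-values, with an offset of 16. Quantile normalization and log2 followed. The background was fitted on 21111 rows whose p-values had not been averaged over probes. Later steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

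Gene names come from the file and were updated through a RefSeq gene table of the GRCr8 assembly, used for names only. Of 21791 rows, 9908 held a current symbol, 4823 were renamed through a synonym, 6943 kept the file's name and 117 had none. Where the current name differs, the file's name is given beside it at first mention. For several rows of a gene the row with the highest mean signal was kept, which left 21480 genes. A gene was detected on a sample at a detection p-value under 0.05. A gene detected on 1 sample of a pair was given a bound: the brighter value against the higher of the other sample's own value and the lowest detected value there. Rows averaged over probes carry averaged detection p-values, so a few bright genes, G0s2 and Angptl4 among them, counted as not detected and have no value in the comparisons.

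The comparisons were high-fat minus standard diet in control and in FR30 offspring, FR30 minus control on each diet, and the difference between both diet differences. Each sample enters 1 diet and 1 prenatal comparison, so a value out of line in 1 sample appears in both, and such differences are not separate results. With 1 sample per group the variation within a group is not known, so no test, standard error or p-value was computed. Genes were counted at 1.5-fold, or 2-fold for the difference of differences, because 4 samples add their errors. The genes named are the 10 largest differences each way among genes detected on both samples, the 3 largest bounds each way, up to 4 members per list, the 5 largest each way for the difference of differences and for the responses shared by both comparisons among genes detected on all 4 samples, and always Scd1, Cpt1a, Pck1, G6pc and Cyp7a1. Fasn and Igf1, on the same list, were not analysed here, and a few other genes that these rules pick are not reported here. Overlaps were set against independent lists of the same sizes. For each of 34 gene lists fixed before the data were examined, the median log2 difference was ranked among 10000 random lists of the same size, matched on mean signal in 20 bins. That percentile describes these samples and is no p-value, since the members of a pathway vary together and random genes do not.

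The functions were tested on simulated data, with noise of the size seen between the high-fat samples and 200 genes given known folds. In the simulated diet comparison in control offspring, run on 9289 genes, 98.0% of 50 genes set at 2-fold and 100% of 50 genes set at 3-fold were called. Of 9016 genes with no difference 0.155% were called, and of 50 genes set at 1.5-fold 56.0%. The simulated noise had the same SD for every gene, 0.127 in log2 per sample, and each of these genes counted as detected on all 4 samples. The simulation therefore holds no bounds and no wider noise for dim genes. Its rates are not the rates of false calls in the counts below. The alternatives planned were the deposited values as they stand, no background correction, an offset of 50, median scaling, detection at 0.01, no detection filter, genes detected on all 4 samples, a 2-fold threshold (1.5-fold for the difference of differences), 3 robust SD of the 500 genes nearest in signal, and the mean of a gene's rows. Alternatives added after seeing the data were the non-normalized values, detection from the signal against negative controls, leaving out genes with a STDEV over 20% of the signal, and requiring intervals of 2 STDEV to be apart. The small number of samples limits the precision of every value.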

Results

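Liver gene expression was compared between adult offspring that differed in prenatal nutrition and in diet. Control offspring and prenatally undernourished offspring, labelled FR30, had been fed a standard or a high-fat diet, which gives 4 groups. Each group was represented by 1 deposited sample of male Wistar rats aged 4 months, so no difference below has a replicate check or a test. Each value is a deposited signal with a STDEV whose number of measurements was not stated. Of 21480 genes, 9220 were detected in the control standard sample, 8996 in the control high-fat sample, 9091 in the FR30 standard sample and 9202 in the FR30 high-fat sample. The summed signal was 19122229, 19124489, 19055511 and 18842096 in the same order, and the median signal lay between 170.1 and 170.6. The median STDEV of a detected gene was 3.16%, 2.89%, 3.68% and 3.57% of its signal.

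The FR30 standard sample differed from the others in its STDEVs. In that sample 114 detected genes had a STDEV over 20% of their signal, against 1, 0 and 0 genes in the control standard, control high-fat and FR30 high-fat samples. These genes included markers of brown and white fat and of skeletal muscle. Fabp4, the fatty acid binding protein of adipocytes, had a signal of 3020.1 with a STDEV of 4928, and Ucp1, the uncoupling protein of brown fat, 1557 with a STDEV of 2452. Acta1 and Ckm, which encode skeletal muscle actin and creatine kinase, read 476 with a STDEV of 543 and 342 with a STDEV of 317. In the non-normalized table, put to genes by row order, the same sample had signals of 168 for Fabp4, 134 for Ucp1, 156 for Acta1 and 153 for Ckm. Differences that rest on these genes are therefore given from both tables below.

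The diet comparison in control offspring asks what the high-fat diet alone went with. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 4.17-fold higher on the high-fat diet, and Scd1 (now Scd), the desaturase that makes monounsaturated fatty acids, was 4.55-fold lower. Hmox1, heme oxygenase, showed the largest difference among genes detected on both samples, at 11.9-fold higher. Genes of cholesterol synthesis were lower as a group: 9 of 20 measured members were at least 1.5-fold lower and 0 higher, with a median log2 difference of -0.45. In all, 248 genes were at least 1.5-fold higher and 322 lower among 9466 compared.

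Among the other genes higher on the high-fat diet in control offspring, the membrane protein Popdc2 was 5.84-fold higher and the transcriptional repressor Bcl6 5.75-fold. The aldehyde dehydrogenase Aldh1a7 was 5.29-fold higher, metallothionein 1 (Mt1, Mt1a in the file) 4.37-fold, and thyroxine-binding globulin (Serpina7) 4.35-fold. The prolactin receptor Prlr was 4.32-fold higher, the fatty acid transporter Cd36 4.07-fold and the chemokine Cxcl13 3.99-fold. Genes detected only in the high-fat sample included the acyl-CoA synthetase Acsm2, at least 12.1-fold higher, Prr15 (RGD1311589 in the file), at least 9.68-fold, and the acyl-CoA thioesterase Acot1, at least 9.14-fold. The largest lower values were those of RGD1564649, a model similar to ribosomal protein S9, 8.87-fold, and of the class I histocompatibility gene RT1-A2, 8.597-fold. Dact1 (RGD1564008 in the file) was 5.79-fold lower, Gadd45g 4.78-fold, and Socs2, an inhibitor of growth hormone signalling, 4.55-fold. Prss32 was 4.26-fold lower, retinol dehydrogenase Rdh16 (Rdh2 in the file) 4.01-fold, LOC316130 3.62-fold and LOC360228 3.52-fold. Bounds in that direction were at least 4.79-fold for the mast cell chymase Cma1, 3.32-fold for cyclin F (Ccnf) and 2.999-fold for Slc25a30.

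Lipid synthesis and glucose lists had lower medians and bile acid genes a higher one in control offspring. Within cholesterol synthesis, Tm7sf2 had a log2 difference of -1.39, Sqle of -1.04 and Dhcr7 of -0.99. Fatty acid and triglyceride synthesis had a median of -0.36, with Elovl5 at -0.84 and Fads1 at -0.81 beside Scd1, and 1 of 14 measured members, Thrsp, at least 1.5-fold higher. Gluconeogenesis had a median of -0.38 over 11 members, with Sds at -1.70 and Gpt at -1.12, and with Pck1 at -0.32 and G6pc (now G6pc1) at -0.13. Glycolysis and glycogen genes had a median of -0.22, with Pklr, which encodes pyruvate kinase, at -0.81. Bile acid genes had a median of 0.29, and Nr0b2, the nuclear receptor that represses Cyp7a1, was higher by 1.504 alongside it. Fatty acid oxidation genes had a median of -0.07 and Cpt1a, which carries fatty acids into mitochondria, read 0.29.

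Zonation, stress and blood markers also differed with diet in control offspring. Genes of the pericentral hepatocyte zone had a median of 0.48, with 3 of 9 members at least 1.5-fold higher, and those of the periportal zone -0.30. Targets of the oxidative stress factor NRF2 had a median of 0.27, with Nqo1 at 0.95 and Gsta3 (Yc2 in the file) at 1.34. Markers of erythroid cells had a median of 0.68, with Ahsp at 1.41, Hbb at 0.74 and Alas2 at 0.62. Female-biased genes had a median of 0.20, antigen presentation -0.28, immediate early genes, which respond to tissue handling, -0.21, male-biased genes -0.17 and xenobiotic metabolism -0.16. Scaled on the medians of detected probes in place of quantiles, the split of this comparison was 173 higher and 468 lower.

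The same diet comparison in FR30 offspring showed Cyp7a1 5.72-fold higher and Scd1 6.62-fold lower on the high-fat diet. Aldh1a7 differed most among the higher genes, at 23.8-fold, with deposited signals of 210.6 in the FR30 standard and 1872.1 in the FR30 high-fat sample. Cholesterol synthesis again held more lower than higher members, 6 against 1 of 20, with a median of -0.24. Tm7sf2 read -1.11 and Sqle -0.68. In all, 369 genes were at least 1.5-fold higher and 324 lower among 9541 compared. From the non-normalized table the counts were 353 higher and 285 lower, and 240 of the 318 genes called lower and held in both tables were lower again.

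Other genes higher on the high-fat diet in FR30 offspring were LOC287167, an alpha globin, 15.2-fold, Gsta3, a glutathione transferase, 9.60-fold, and Acot1 9.43-fold. Deposited signals in the FR30 standard and high-fat samples were 184.4 and 881.3 for LOC287167 and 185.2 and 612.8 for Gsta3. Negative controls of the FR30 standard sample averaged 154, so the size of these folds depends on the background correction. In the non-normalized table LOC287167 was not detected in that sample, with a log2 bound of at least 3.87. Birc6 was 7.19-fold higher, Rnf113a2 (Znf183 in the file) 7.16-fold, RGD1564649 6.76-fold, the cadherin Cdh17 5.39-fold and Prr15 5.05-fold. Birc6 read 1019.7, 864.8, 259.6 and 1012.5 in the control standard, control high-fat, FR30 standard and FR30 high-fat samples. Its low FR30 standard value gives both this difference and the prenatal difference on the standard diet. Prr15 had a STDEV of 45.7 on a signal of 209.9 in the FR30 standard sample, and its log2 difference was 2.82 in the non-normalized table. Bounds were at least 7.31-fold for Acsm2, 6.81-fold for the sodium channel subunit Scnn1a and 5.42-fold for Plekhf2. Lower genes with small STDEVs were Cavin3 (Prkcdbp in the file) 5.53-fold, RGD1563706 4.84-fold, Socs2 4.10-fold, the hepatocyte transcription factor Onecut1 4.00-fold and RGD1562971 3.93-fold. The other lower values of the largest size were those of genes with wide STDEVs in the FR30 standard sample: Fabp4 26.3-fold, Ldhb 6.94-fold, Adipoq 5.24-fold and Adrb3 4.88-fold, with bounds of 37.3-fold for Ucp1 and 10.2-fold for LOC497667. In the non-normalized table Fabp4 and Adipoq were not detected in the FR30 standard sample, with log2 bounds of at least 1.11 and 0.06. Ldhb and Adrb3 had log2 differences of 0.27 and -0.09 there. Scd1, whose FR30 standard signal of 23229.5 had a STDEV of 9851.7, stayed lower, at a log2 difference of -2.25. Adipocyte markers had a median of -1.81 over 4 measured members in the normalized table and 0.26 over 3 in the non-normalized table.

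By list, the pericentral zone had the highest median in FR30 offspring apart from blood markers, 0.70 with 6 of 9 members at least 1.5-fold higher, among them the glutamate transporter Slc1a2 at 1.93, Tbx3 at 1.26 and Rhbg at 1.06. The periportal zone read 0.03. Erythroid markers had a median of 0.80, with Ahsp at 1.78. Bile acid genes had a median of 0.19, with Nr0b2 at 1.44 and Cyp7b1 at 1.43, and gluconeogenesis -0.45, with G6pc at -0.83, Pck1 at -0.53 and Cpt1a, of fatty acid oxidation, at -0.14. Interferon response genes had a median of -0.47: Mx2 read -1.38, Irf7 -1.19 and Oas1a -1.03, against Ifit2 at 0.99. Cell cycle genes had a median of -0.35, with Mcm6 at -1.66 and cyclin D1 (Ccnd1) at -1.55. Urea cycle and amino acid genes had a median of 0.32, female-biased genes 0.43, NRF2 targets 0.14, lymphocyte markers -0.29, antigen presentation -0.25 and cytokines -0.25. Fatty acid synthesis had a median of -0.03 in the normalized and 0.18 in the non-normalized table, lipid droplet and lipoprotein genes -0.22 and -0.06, and stellate cell and matrix markers -0.41 and -0.02.

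**Figure D1:**
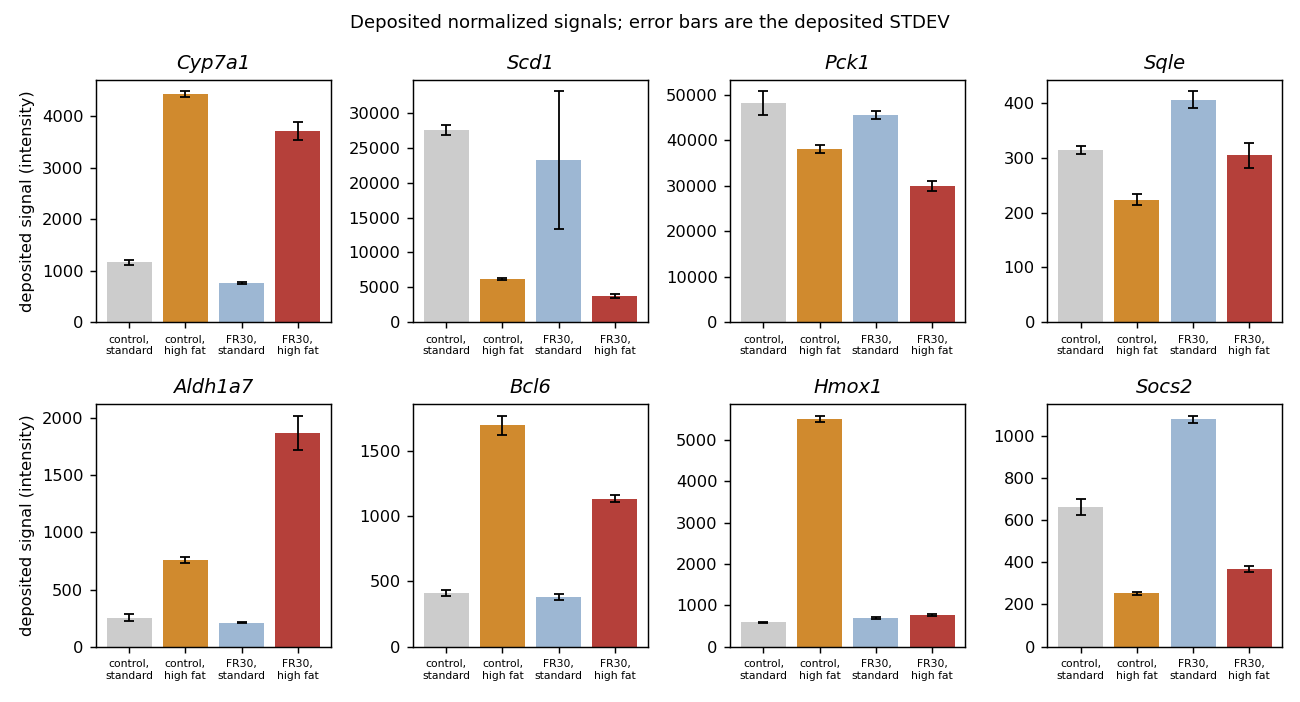
Deposited normalized signal (intensity, vertical axes starting at 0) of 8 genes in the 4 samples, with the deposited STDEV as error bars. Cyp7a1, Aldh1a7 and Bcl6 stood higher and Scd1 and Socs2 lower on the high-fat diet in control and FR30 offspring, Hmox1 was high in the control high-fat sample, and the STDEV of Scd1 was wide in the FR30 standard sample.

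The diet differences of control and FR30 offspring come from separate samples, so their overlap tells how far the differences between diets recurred. Anything else that both samples of a diet shared would add to this overlap and cannot be told apart from diet. Among genes detected on all 4 samples, which leaves out bounds such as those of Acot1 and Acsm2, Aldh1a7, Cyp7a1, Bcl6, the lipoxygenase Alox15 and histidine decarboxylase (Hdc) led the genes higher in both, by at least 5.29-fold, 4.17-fold, 4.10-fold, 3.61-fold and 3.19-fold. Within the same genes, which leaves out Prss32 and Ccnf, Scd1, Socs2, Dact1, LOC316130 and RGD1563706 led those lower in both, by at least 4.55-fold, 4.10-fold, 3.70-fold, 3.62-fold and 2.83-fold. Of 9153 genes compared in both, 104 were at least 1.5-fold higher in both and 85 lower in both. Independent lists of these sizes would share 9.54 and 10.1. A further 33 genes differed in opposite directions, against 20.1 for independent lists. Cfd, Cidea and Itm2a among them had wide STDEVs in the FR30 standard sample, and from the non-normalized values 21 genes differed in opposite directions. Across 8457 genes, which are not independent replicates, Pearson r was 0.33 and Spearman rho 0.279, and 59.7% had the same sign.

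**Figure D2:**
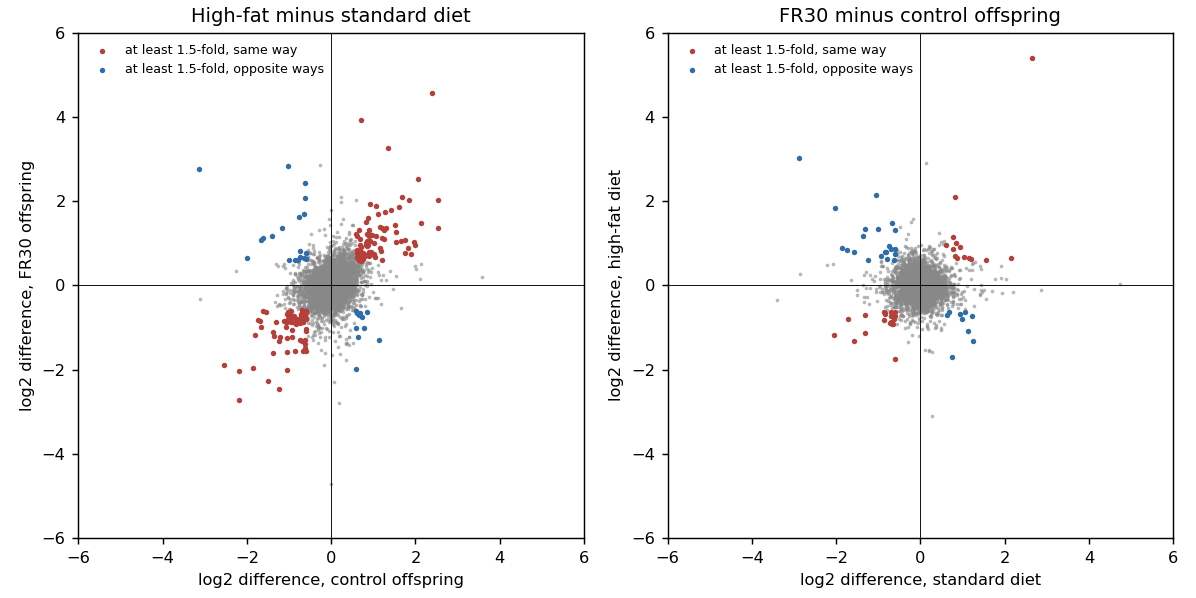
Log2 differences of the 8457 genes detected on all 4 samples: left, high-fat minus standard diet in control (horizontal) against FR30 offspring (vertical); right, FR30 minus control offspring on standard (horizontal) against high-fat diet (vertical). Red points were at least 1.5-fold the same way in both and blue points opposite ways; r was 0.33 for diet and -0.03 for prenatal undernutrition.

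FR30 minus control offspring on the standard diet asks what prenatal undernutrition went with before any dietary load. Single enzymes of steroid and drug metabolism were lower in the FR30 sample: the female-biased cytochrome Cyp2c12 was 4.15-fold lower, the glucuronosyltransferases Ugt2b17 and Ugt2a3 3.61-fold and 3.35-fold, and Akr1c2 (Akr1c21 in the file) 3.28-fold. On the high-fat diet Ugt2b17 and Ugt2a3 went the other way, with log2 differences of 0.89 and 0.84, while Cyp2c12 and Akr1c2 were lower again. The xenobiotic metabolism list as a whole had a median of 0.00, with 0 of 11 members at least 1.5-fold higher and 1 lower. Immediate early genes were also lower, 7 of 13 at least 1.5-fold and 0 higher, with a median of -0.60. Of the 10 largest higher values 9 belonged to genes with wide STDEVs, Fabp4 and Adipoq of adipocytes among them, and 2 of the 10 were also at least 1.5-fold higher in the non-normalized table. In all, 202 genes were at least 1.5-fold higher and 213 lower among 9520 compared; without genes whose STDEV exceeded 20% of the signal, the counts were 136 and 213. Requiring intervals of 2 STDEV to be apart left 113 higher and 186 lower, and the non-normalized table gave 133 and 187.

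The lower genes on the standard diet began with Cdh17, 10.5-fold, RGD1564649, 7.39-fold, Birc6, 7.23-fold, caspase 12 (Casp12), 4.64-fold, Gadd45g, 4.22-fold, and Rnf113a2, 4.09-fold. Cdh17, RGD1564649, Birc6 and Rnf113a2 were also among the genes higher with diet in FR30 offspring, which shares the FR30 standard sample. Gadd45g was also among the genes lower with diet in control offspring, which shares the control standard sample. Bounds were at least 4.88-fold for Cma1, 4.43-fold for Scnn1a and 3.11-fold for Sdr16c6 (RGD1562060 in the file). Among the 9 higher genes with a STDEV over 20% of the signal, Fabp4 was 26.7-fold higher, Ldhb 7.31-fold, adiponectin (Adipoq) 5.49-fold, the beta-3 adrenergic receptor Adrb3 4.58-fold, the lipid droplet protein Cidea 4.43-fold, Lgals1 4.11-fold, Rgs2 3.85-fold, gelsolin (Gsn) 3.75-fold and Aoc3 3.74-fold. Bounds were at least 38.8-fold for Ucp1 and 10.6-fold for LOC497667. In the non-normalized table Fabp4 was not detected in the FR30 sample, which gives a log2 bound of -1.06 or lower. The FR30 signals of Adipoq, Ucp1 and LOC497667 there were 175, 134 and 139, against 179, 156 and 144 in the control standard sample. The log2 differences were -0.20 for Ldhb, 0.00 for Adrb3, 0.42 for Lgals1, -0.17 for Rgs2, -0.13 for Gsn, 0.06 for Aoc3 and 0.74 for Cidea. LOC499823, a model similar to LRRGT00001, was 6.28-fold higher with a STDEV of 174 on a signal of 3625, and its log2 difference was 2.66 in the non-normalized table.

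**Figure D3:**
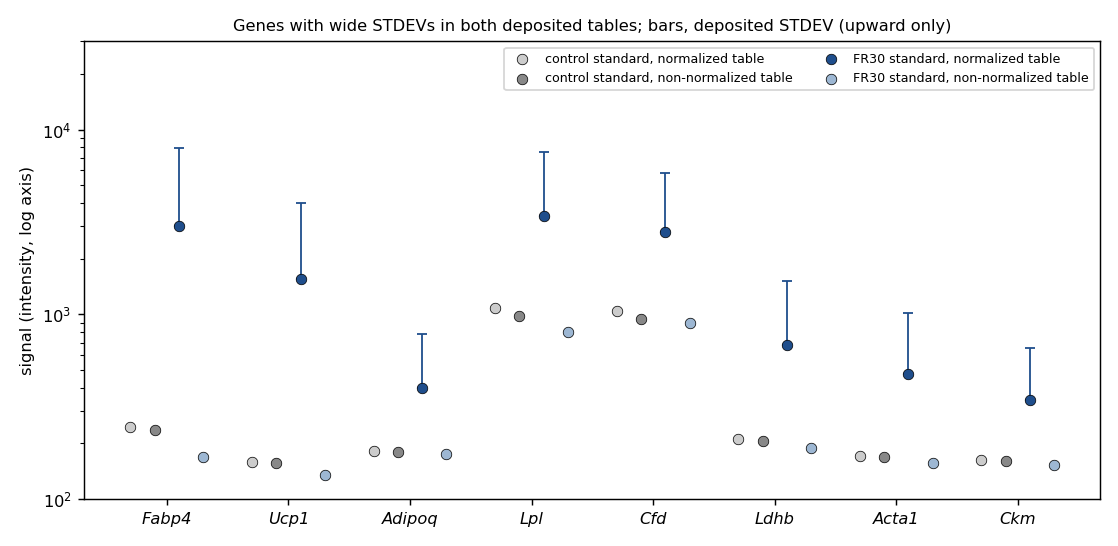
Signal (intensity, log axis) of 8 genes with wide STDEVs in the control standard and FR30 standard samples, from the normalized and the non-normalized table, with the deposited STDEV drawn upward for the normalized FR30 value. In the FR30 sample Fabp4 read 3020.1 in the normalized and 168 in the non-normalized table.

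Of the gene lists on the standard diet, endoplasmic reticulum stress genes had a median of 0.27, with Dnajb9 at 0.81, Herpud1 at 0.75 and Creld2 at 0.57, and with Chac1 at -1.08. Female-biased genes had a median of -0.51, with Sult2a6 (Smp2a in the file) at -0.74, although Prlr read 1.22. Among immediate early genes Junb read -0.87, Gadd45a -0.83, Jun -0.81 and Btg2 -0.65. Circadian clock genes had a median of -0.26, with Npas2 at -0.80 and Per1 at 1.12, the periportal zone -0.23, urea cycle genes -0.18, glycolysis -0.16 and oxidative phosphorylation -0.06. Interferon response genes had a median of 0.16. Adipocyte markers had a median of 2.004, stellate cell and matrix markers 0.23, endothelial markers 0.30, lymphocyte markers 0.23 and lipid droplet genes 0.11. In the non-normalized table, with 2 adipocyte markers measured, these read -0.50, -0.07, 0.09, 0.15 and 0.05. Scd1 read -0.19, and -0.65 in the non-normalized table, Cpt1a 0.33, Pck1 -0.05, G6pc 0.22 and Cyp7a1 -0.70. Under median scaling the split was 168 higher and 273 lower.

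FR30 minus control offspring on the high-fat diet asks what prenatal undernutrition went with under the dietary load, and holds any difference already present on the standard diet. Genes of cholesterol synthesis and uptake were higher in the FR30 sample, 8 of 20 at least 1.5-fold and 0 lower, with a median of 0.42. On the standard diet the same list had a median of 0.09, with 1 of 20 members higher and 0 lower. The control high-fat sample also enters the lower median of this list with diet in control offspring, so these are not separate results. Hmox1 was 8.61-fold lower, since it was high in the control high-fat sample alone. The nuclear receptor Nr1i3, which controls drug metabolism, was 2.61-fold higher, and Lox, which cross-links collagen, 3.22-fold lower. In all, 177 genes were at least 1.5-fold higher and 150 lower among 9430 compared.

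Within cholesterol synthesis on the high-fat diet, Sqle read 0.96, Fdft1 0.95 and Dhcr7 0.81. Fatty acid synthesis had a median of 0.24, with Fads1 at 1.24 and Fads2 at 0.78 against Scd1 at -0.73. The other higher genes were LOC499823, 42.2-fold, RGD1564649, 8.11-fold, RT1-A2, 7.46-fold, LOC287167, 4.42-fold, and Zcchc9, 4.26-fold. RT1-A2 read 4354.7, 627.7, 4705.3 and 3787.1 in the control standard, control high-fat, FR30 standard and FR30 high-fat samples. Its low control high-fat value gives both this difference and the lower value with diet in control offspring. Rnf113a2 was 3.57-fold higher, LOC368066 2.96-fold, the peroxisomal thiolase Acaa1b (RGD1562373 in the file) 2.84-fold and Aldh1a7 2.80-fold. The bounds were at least 3.76-fold for Fn3krp (RGD1304570 in the file) and 3.19-fold for Pbsn. Among lower genes, the immediate early factor Egr1 was 3.38-fold lower. Class I histocompatibility genes and models followed, RT1-CE16 at 2.98-fold, RGD1562652 at 2.93-fold and RT1-S2 at 2.91-fold, beside LOC502176 at 2.91-fold, Mybl1 at 2.55-fold, RGD1562971 at 2.51-fold and Epha4 (RGD1560587 in the file) at 2.505-fold. Bounds were at least 4.63-fold for LOC310926, 3.75-fold for LOC497812 and 1.98-fold for Tacr1.

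Other lists were higher or lower on the high-fat diet. Insulin, growth hormone and IGF signalling had a median of 0.17, with Socs2 at 0.998, urea cycle genes 0.16 and the periportal zone 0.14. Cytokines had a median of -0.23, with Cxcl10 at -0.97, antigen presentation -0.19, with RT1-Ba at -0.84, and lymphocyte markers -0.32. Oxidative phosphorylation had a median of 0.06, with 0 of 27 members past 1.5-fold in any of the 4 comparisons. Cyp7a1 read -0.24, Cpt1a -0.09, Pck1 -0.26 and G6pc -0.48. Under median scaling the split was 235 higher and 108 lower.

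**Figure D4:**
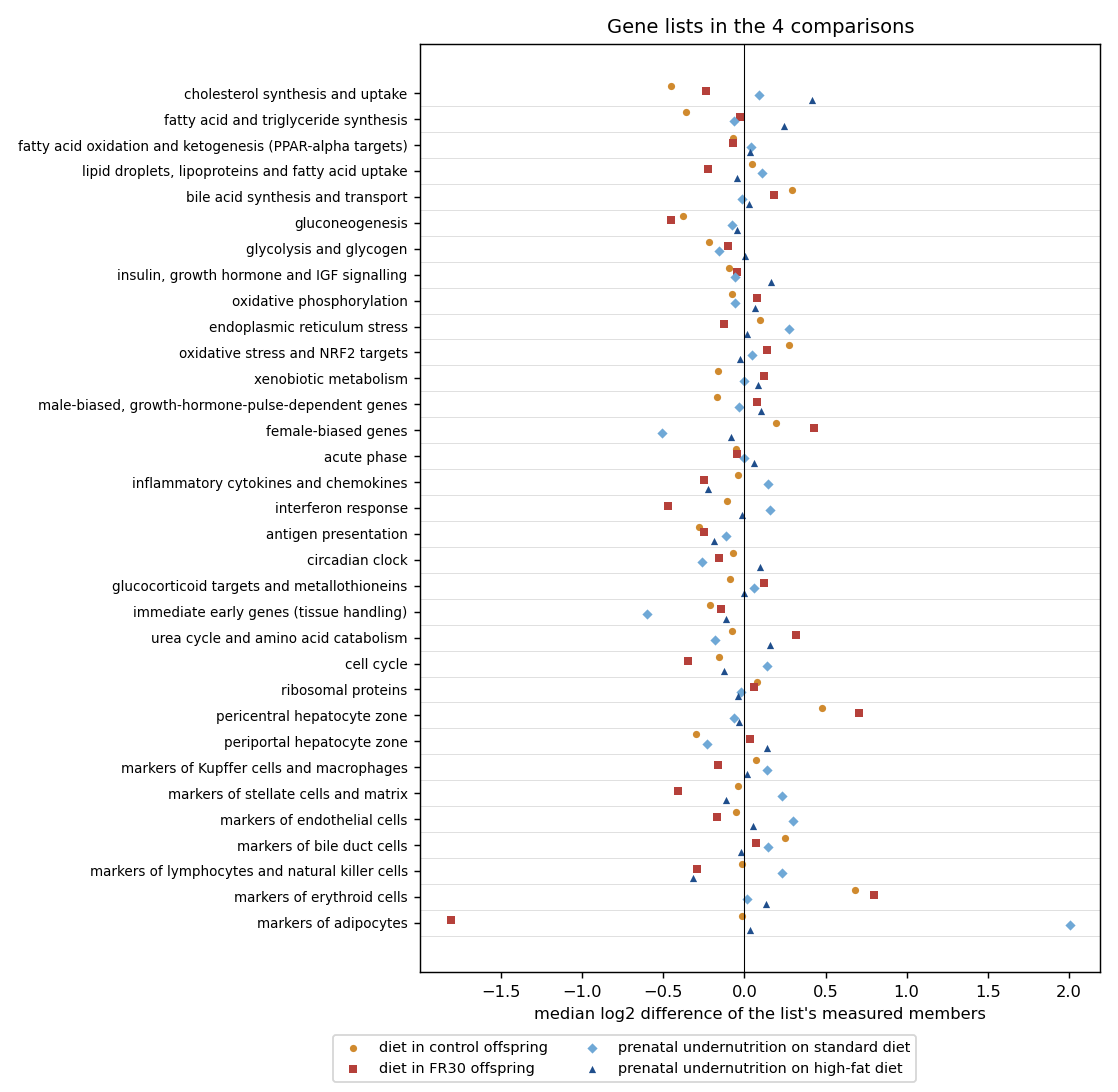
Median log2 difference (horizontal axis) of each gene list with at least 3 measured members, in the 4 comparisons (symbols). Cholesterol synthesis lay at -0.45 and -0.24 for diet in control and FR30 offspring. For FR30 minus control it lay at 0.09 on the standard and 0.42 on the high-fat diet. The adipocyte markers at -1.81 and 2.004 rest on the FR30 standard sample and its normalized signals.

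Few prenatal differences recurred on both diets. Among genes detected on all 4 samples, LOC499823, the water channel Aqp1, Socs2, Zcchc9 and LOC362882 were the largest that were higher on both, by at least 6.28-fold, 1.89-fold, 1.80-fold, 1.76-fold and 1.72-fold. Epha4, Cyp2c12, the fructose transporter Slc2a5, Esm1 and Akr1c2 were the largest that were lower on both, by at least 2.505-fold, 2.26-fold, 2.19-fold, 1.75-fold and 1.74-fold. Of 9104 genes, 16 were higher in both and 25 lower in both, against 3.16 and 3.30 for independent lists, and 35 went opposite ways, against 6.54. Since opposite ways also exceeded independent lists, the excess of genes going the same way does not by itself show a recurring prenatal difference. Across genes, Pearson r was -0.03 and Spearman rho -0.0505, and 47.9% had the same sign.

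The difference of the diet differences was at least 2-fold for 184 of 8457 genes, 93 of them with the higher value in FR30 offspring and 91 with the lower. RGD1564649 led the first with a log2 value of 5.91, followed by Rnf113a2 at 3.87, LOC287167 at 3.21, Birc6 at 3.12 and Cdh17 at 3.05. Fabp4 at -4.70 and Ldhb at -2.99 had the lowest values together with Hmox1 at -3.39, RGD1562971 at -2.57 and Lox at -2.44. Fabp4 and Ldhb rest on the wide STDEVs of the FR30 standard sample: in the non-normalized table Ldhb read 0.09 and Fabp4 was not detected in that sample. Without genes of wide STDEV 70 genes had the lower value in FR30 offspring and 93 the higher. Under median scaling in place of quantiles, 68 genes had the lower value and 142 the higher, so the even split depends on the scaling. Of the variation between the 4 samples over the 8457 genes, 50.5% lay along diet, 24.1% along prenatal undernutrition and 25.5% along their combination. Noise alone would give each 33.3%, and the size of the noise was not measured between samples.

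The medians of the remaining lists are given for diet in control, diet in FR30, and FR30 minus control on standard and on high-fat diet in that order. Acute phase genes had medians of -0.05, -0.05, 0.00 and 0.06, glucocorticoid targets and metallothioneins -0.09, 0.12, 0.06 and -0.01, and ribosomal proteins 0.08, 0.06, -0.02 and -0.04. Markers of Kupffer cells and macrophages read 0.07, -0.16, 0.14 and 0.02 and bile duct markers 0.25, 0.07, 0.14 and -0.02. For pancreatic acinar cells 2 of 8 markers were measured, with medians of 0.05, 0.38, -0.32 and 0.01. Of 132 list medians with a percentile, 54 lay in the outer 5% of their random lists, where random lists would give 6.60. By comparison these were 15, 16, 14 and 9.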

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

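The tests of the fat and muscle genes and of the genes with the largest difference of differences were chosen after those results were seen; the tests of the prenatal correlation were set before their values were.

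The deposited STDEVs, which the main setting does not use as an error, show 114 genes with a STDEV over 20% of the signal in the FR30 standard sample, against 1 gene in the control standard sample. Of these, 108 were higher there than in the control standard sample. In the 2 diet comparisons 33 genes were at least 1.5-fold different in opposite directions, and in the 2 prenatal comparisons 35 were. For diet, independent lists would give 20.1, and the non-normalized values gave 21. These differences between groups were not tested, since each group has 1 sample.

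Fat and muscle genes in the FR30 standard sample form the first pattern. If 1 of n arrays averaged into a sample carries a transcript that the others lack, the STDEV divided by the rise in the mean is the square root of n. Over the 4 adipocyte markers detected there this ratio had a median of 1.71, where 3 arrays give 1.73. A higher level in every array is argued against, since the lowest ratio among these markers was 1.59. Of 13 macrophage and endothelial markers 0% had a wide STDEV. That does not decide on a general loss of hepatocytes, since background in the deposited signals lowers the STDEV as a percent of the signal. Against the control standard sample, endothelial markers had a median log2 difference of 0.30, and of 0.09 in the non-normalized table. Macrophage markers had medians of 0.14 and 0.10. Of the genes with a STDEV above 50% of the signal 39 had 1 value in the non-normalized table and lay there below the normalized value by a median of 0.579 STDEV (range 0.568 to 0.584), where leaving 1 of 3 arrays out gives 0.577, so fat and muscle tissue in 1 of 3 arrays, absent from the non-normalized column, may explain the pattern.

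The second pattern is the absence of a correlation between the prenatal differences on both diets, at r = -0.03. Without genes of wide STDEV r was -0.0359, which argues against fat and muscle transcripts hiding a shared difference. In the 2115 brightest genes r was -0.0091, against 0.365 for diet in the same genes, which argues against noise of dim genes as the reason. A prenatal difference that depends on diet could give this pattern, and so could chance differences between the rats of each group; neither was tested.

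The third pattern is a set of 16 genes with a difference of differences of at least 4-fold in the positive direction, among them RGD1564649 with Rps9, RT1-A2 and LOC499823. A variant carried by some of the rats averaged into a sample would give wide STDEVs if each array held 1 rat. Of the 16 genes 0 had a STDEV over 20% of the signal in any sample, and the median of their highest STDEV was 6.46% of the signal. Few detected genes of any kind passed this limit, 114 in the FR30 standard sample and at most 1 in each other sample. Inherited variants stay open if each sample holds 1 rat or 1 pool measured several times. They also stay open if all rats of a sample carried the same variant. A combined effect of prenatal nutrition and diet also stays open and was not tested.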

How the results depend on the processing

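The non-normalized values, detection from the signal, the limit on STDEV and the intervals of 2 STDEV were chosen after seeing the data. Counts are given as higher and lower for diet in control, diet in FR30, prenatal on standard diet, prenatal on high-fat diet and the difference of differences, then as same and opposite ways for the diet and the prenatal overlap. On the deposited values they were 111 and 136, 164 and 136, 85 and 70, 60 and 44, 45 and 27, then 92 and 9, and 9 and 13. Without background correction they were 110 and 135, 163 and 136, 84 and 72, 60 and 44, 45 and 27, then 92 and 9, and 9 and 13. With an offset of 50 they were 128 and 167, 188 and 173, 106 and 96, 77 and 59, 51 and 38, then 103 and 14, and 14 and 17. A 2-fold threshold gave 68 and 79, 115 and 105, 65 and 47, 29 and 24, then 54 and 7, and 5 and 8, and a 1.5-fold threshold gave 409 and 359 for the difference of differences. These settings count fewer or more genes by construction. Uncorrected background or a larger offset shrinks folds, and a changed threshold moves the limit itself. A threshold of 3 robust SD moved diet in control to 157 and 212, diet in FR30 to 234 higher, the difference of differences to 180 and 150 and the diet overlap to 118 and 15. Median scaling moved the difference of differences to 142 higher, beside 68 lower. The cause was not tested.

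From the non-normalized values, prenatal on standard diet had 133 genes higher and the diet overlap 21 opposite ways. Intervals of 2 STDEV left 113 genes higher for prenatal on standard diet. Results that turned did so in the non-normalized table alone, where the FR30 standard sample lacks the high signals of the adipocyte markers. For diet in FR30 Fabp4 read 1.11, Ldhb 0.27, Adipoq 0.0644, Lpl 0.73, Pnpla2 0.0256, Cidea 0.75, Cfd 0.26 and the adipocyte list 0.26. For prenatal on standard diet Fabp4 read -1.06, Ldhb -0.20, Rgs2 -0.17, Gsn -0.13, Thrsp -0.47, Lpl -0.20, Pnpla2 -0.16, the adipocyte list -0.50 and the stellate list -0.0749. Ldhb read 0.0859 for the difference of differences. The values of Fabp4, and of Adipoq, are bounds. The other counts, both correlations and the shares of variation moved by less than 1.5 times or their resampling interval over genes. Over all settings 2823 values of the 332 named differences stayed, 683 moved and 15 turned, and of the 136 list medians 1353 values stayed, 136 moved and 3 turned. Folds of dim genes depend on the background: Acsm2, diet in control, has a bound of 3.59 in log2 from deposited signals of 695 and 180.3, and a smaller difference without the correction. Signals near background limit the smaller folds: 9862 of 21480 genes were detected on any sample.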

Other observations

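Each observation here was chosen after its values were seen. Single genes of the insulin, growth hormone and IGF list differed with diet in control and FR30 offspring, while the list as a whole had medians of -0.09 and -0.04, with 2 higher and 2 lower of 12 members and 2 higher and 1 lower. Igfbp1, which binds IGF and is repressed by insulin, had log2 differences of 1.60 and 1.86, and Igfbp2 of at least 2.32 and of 1.497. Socs2, a target of growth hormone, read -2.19 and -2.04. The circadian repressor Nr1d1 read at least 1.56 and 1.46, whereas Per1 read 1.66 in control and -0.54 in FR30 offspring. Cd14, the lipopolysaccharide receptor of macrophages, read -0.30 and 1.31.

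The shape of the STDEVs also bears on how many arrays lie behind each sample. The 5th percentile of the STDEV, taken as a percent of the signal, was 0.259, 0.257, 0.259 and 0.265 of its median in the control standard, control high-fat, FR30 standard and FR30 high-fat samples. Normal values give 0.093 for 2, 0.272 for 3 and 0.386 for 4 measurements. The 95th percentile was 2.36, 2.24, 2.49 and 2.26 of the median, between the 2.91 of 2 and the 2.08 of 3 measurements, so the shape does not settle the number. Beside the ratio of 1.71 for the adipocyte markers in the FR30 standard sample, 3 arrays per sample may lie behind the deposited means; whether these were separate rats was not tested.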
